A study of Mus musculus with 8 samples.

How the data were processed

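RNA sequencing of P19 cells covered 2 siRNA arms at 4 times after actinomycin D, 8 conditions in all. Reads were aligned with TopHat2 and expression was estimated with Cufflinks on the mm10 build, per the submitters' processing notes, which give no versions; the annotation is not given in the sources used here. Total RNA was extracted with Trizol and libraries followed standard Illumina protocols, per the labels' protocols. The deposited table gives 1 FPKM value (fragments per kilobase of transcript, scaled for sequencing depth) per gene and condition for 23284 genes, per the file headers, with a lower and an upper confidence limit whose level is not stated and a status field. The labels list 2 cultures for each condition, so the authors combined these before deposit; how is not stated, nor is whether the libraries were scaled to each other across conditions. The median-of-ratios shifts between conditions were small (-0.036 to 0.041 log2 units) while FPKM totals differed, so such a scaling is possible. Conditions were matched to table columns by arm and time in the column names. Of the table's genes, 3 had a failed status in 3 knockdown conditions (0, 105 and 225 min), and 18 to 25 genes per condition had an upper limit below the FPKM. No gene lay on the mitochondrial chromosome, and mitochondrially encoded genes were not analysed here.

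The FPKM is not a count and the depth is unknown. Low values showed no steps of whole reads: the most frequent bin of 0.05 log2 units held 2.7% to 4.9% of low genes. Loci shared by several genes numbered 1811 and held 4287 genes, whose reads may be split between them. FPKM has no outside standard, so a fall in total mRNA after transcription stops is not seen and each slope is relative to the bulk.

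Analysis used R 4.3.3 with limma 3.58.1, and Python 3.11.15 for reading the table. Values were taken as log2(FPKM + 1) for the 11452 genes with a mean FPKM of 1 or more, and Benjamini-Hochberg adjusted p below 0.05 was the threshold, with eBayes without trend. The expression difference was fitted with time point as a factor plus arm, with 3 residual degrees of freedom. The decay rate difference was the arm-by-hours term with time point as a factor, with 2 residual degrees of freedom, and a negative value means faster loss in the knockdown arm. The decay rate in both arms was the slope over hours with arm as a term, with 5 residual degrees of freedom, and a relative half-life is 1 divided by the negative slope. Since each condition has 1 value, residuals measure disagreement between time points, not between cultures, and p-values cover that spread only. The targeted gene was tested with an exact sign-flip test over 4 time points.

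The design, the alternatives, the rule for named genes and 21 gene lists were fixed before the data were examined. The lists are NMD factors, exon junction complex, known NMD targets, snoRNA host genes, poison-exon splicing factors, stress and unfolded protein response, short-lived mRNAs, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, replication-dependent histones, glycolysis, cholesterol synthesis, pluripotency, neural differentiation, mesoderm and endoderm, fibroblast and smooth muscle markers, p53 targets, interferon response, cell cycle and RNA decay machinery. Members under older names were matched through synonyms, 12 in all. Lists of 5 or more tested genes were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. With an estimated correlation camera uses the few residual degrees of freedom of the fit, so its p has little power here. The NMD target and snoRNA host lists were also placed among 10000 random lists matched on mean expression in 20 bins, with two-sided permutation p. The permutation p takes no account of correlation between genes.

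Named genes are the 10 largest positive and 10 largest negative effects among called genes with a mean FPKM of 5 or more and the same sign at all times or in both arms, filled by moderated t where fewer passed, and up to 4 members per list by moderated t, with Upf3a and Upf3b always. Symbols of predicted genes, small RNAs, pseudogenes and clone names ending in Rik were left out; the text names a part of the list members and of the genes filled in by t, chosen after their values were seen, and some genes that the rule picks are not reported. Mir3096 lies outside this rule and was named after its values were seen. Coordinates, transcript length, GC content and 3' UTR length came from GENCODE vM21 on GRCm38, which matched 98.9% of tested genes.

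The fits were checked on simulated data for 11452 genes, 200 of them changed. For the expression difference, 99% of genes changed by 0.5 log2 units and 100% of those changed by 1 were recovered. For the decay rate difference the shares were 0% at 0.1 and 90% at 0.3 log2 units per hour, and for the decay rate in both arms 39% and 95%. False calls were 3.4%, 6.2% and 4.3% of all calls. Simulated errors were independent between genes and conditions. A difference shared by the time points of an arm was not simulated, so these shares do not cover it.

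The alternatives were pseudocounts of 0.1 and 5, no filter and a mean FPKM of 5 or more, median-of-ratios scaling, quantile normalization, scaling to ribosomal protein genes, eBayes with trend, leaving out each time point, an adjusted p below 0.1, time linear in each arm, the last minus the first ratio, slopes from 15 min on, and other list tests. Quantile normalization gives all conditions the same distribution of values, so a shared change of the most abundant mRNAs is partly removed by construction. Ribosomal protein mRNAs held 152255 of 562848 FPKM in the control arm at 0 min. Non-overlapping limits of the authors, removal of length and GC trends and leaving out small RNA genes were added after seeing the data. The authors' own significance calls were planned but q-values are not used here, and fits on single replicates were not run because the table holds 1 value per condition.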

Results

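RNA was sequenced from P19 cells, a mouse embryonal carcinoma line that resembles cells of the early embryo, after transfection with a control siRNA or an siRNA against Upf3a. Upf3a encodes a factor of nonsense-mediated decay (NMD), the pathway that degrades mRNAs whose stop codon is read as premature. A day after transfection transcription was blocked with actinomycin D, and RNA was taken at 0, 15, 105 and 225 min, so that the fall of an mRNA over time reflects its stability. The 2 arms and 4 time points make 8 conditions. The labels list 2 cultures for each, and the deposited table holds 1 FPKM value per gene and condition, so n below counts time points and there is no separate replicate. FPKM totals ran from 537350 to 923333 per condition, 10832 to 11600 genes had an FPKM of 1 or more, and read depth is unknown. The authors' upper limit lay a median of 29.8% to 30.3% above the FPKM.

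Upf3a mRNA was lower in the knockdown arm at all 4 time points. The gene lies on chromosome 8 at 13785615 to 13799193 (plus strand, GRCm38). It averaged 14.1 ± 0.60 FPKM in the control arm and 4.68 ± 0.47 FPKM in the knockdown arm (mean ± SD, n = 4 time points), which is 33.1% of control. The mean log2 ratio was -1.42 (SD 0.17, n = 4 time points), and the authors' limits of the arms did not overlap at any of the 4 times. An exact two-sided sign-flip test gave p = 0.12, the smallest p that 4 pairs allow (rounded). Upf3b, the paralog that acts in NMD (X chromosome, 37091678 to 37110322, minus strand), averaged 13.5 ± 3.34 and 10.7 ± 2.44 FPKM, 79.6% of control, and its limits overlapped at each time. It was also lower at all 4 times, with a mean log2 ratio of -0.30 (SD 0.15) and the same sign-flip p of 0.12.

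**Figure D1:**
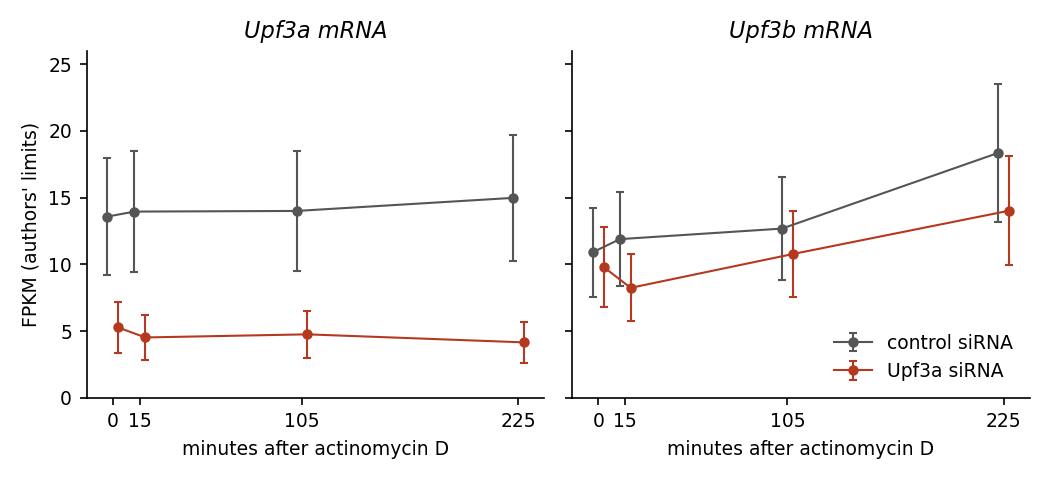
FPKM of Upf3a (left) and Upf3b (right) against minutes after actinomycin D, with control siRNA in grey and Upf3a siRNA in red; bars are the authors' confidence limits, and points are shifted sideways for clarity. Upf3a averaged 14.1 FPKM in the control arm and 4.68 FPKM in the knockdown arm.

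The first comparison asked which mRNAs differed in level between the arms at all times. Among called genes with a mean FPKM of 5 or more, one sign at all times and a symbol inside the naming rule, the largest increases included Fgf5, a growth factor of early embryonic cells, at 2.62-fold (9.30 ± 3.40 against 2.89 ± 1.13 FPKM), Mmachc, an enzyme of cobalamin metabolism, at 2.51-fold (20.6 ± 2.34 against 7.60 ± 0.93 FPKM), and BC055324 at 2.88-fold (18.5 ± 3.49 against 5.89 ± 1.83 FPKM). The largest decreases of this kind were Cd209c, a C-type lectin gene, at 37.1 ± 18.5 against 141 ± 70.9 FPKM, and the antisense transcript 6430548G04 at 3.78 ± 2.16 against 15.0 ± 8.70 FPKM. Over all 11452 genes tested, 2986 were called higher and 2557 lower, and list counts here and below are to be read against these. Of 23 cholesterol synthesis genes 18 were lower in the knockdown arm, while 14 of 28 pluripotency genes, 9 of 17 early mesoderm and endoderm genes and 15 of 26 splicing factors with poison exons were higher. These lists passed camera at its preset correlation but not with an estimated correlation (adjusted p = 0.44, 0.44, 0.44 and 0.63 with an estimated correlation). They also passed fry, which tests each list alone and not against other genes (adjusted p = 0.0016, 7.5e-04, 0.0016 and 0.017). The estimated correlations were 0.045, -0.022, -0.012 and 0.22 in the same order, against the preset 0.01. For the pluripotency list and the mesoderm and endoderm list, correlation between members therefore does not account for the higher p with an estimated correlation. For all lists, that form of camera also uses the 3 residual degrees of freedom of this fit, so it has little power. Values are mean ± SD over 4 time points, and folds are on the log2(FPKM + 1) scale, which understates changes of low genes.

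Of 11452 genes tested, limma called 5543, with 2986 higher and 2557 lower in the knockdown arm at an adjusted p below 0.05. The balance of directions depends on the scaling: 3758 were higher and 1276 lower when scaled to ribosomal protein genes, 2632 and 3046 with median-of-ratios scaling, 2757 and 3170 after quantile normalization, and 2784 and 3073 without length and GC trends. Most of the differences were small: the median size among called genes was 0.27 log2 units, and 66 genes differed by 1 log2 unit or more, 50 of them higher and 16 lower. The sign of the log2 ratio was the same at all 4 times for 6917 genes, 60.4% of those tested, where chance gives 12.5%. By the stricter criterion that the authors' limits do not overlap, 33 genes were higher and 10 lower at all 4 times. All 43 were called by limma from the same values, which is no separate support for its calls. The spread in this test is the disagreement between time points: whether time points of an arm came from the same transfection is not stated in the labels, and a difference between transfections would repeat at each time.

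Within the same limits on FPKM, sign and symbol, the other largest increases were Cdkn2aipnl (log2 difference 1.23), the splicing factor Rbm25 (1.22), the lamin gene Lmnb2 (1.20), the RNA polymerase III subunit Crcp (1.15), Neurl4 (1.14), the transcription factor Rfx1 (1.14) and Tmem150a (1.11). The other largest decreases within them were Tcf19 (-1.15), the transcription factor Sp4 (-1.10), Prrg2 (-0.98), Id2, an inhibitor of helix-loop-helix factors (-0.97), cyclin G2 or Ccng2 (-0.96), the cytokine Il33 (-0.92) and Arhgef3 (-0.86). Adjusted p lay between 4.7e-05 and 1.8e-04 for the 20 genes by limma. On GRCm38, BC055324 lies on chromosome 1 at 163945993 to 163994796 (minus strand), Fgf5 on chromosome 5 at 98254184 to 98277030 (plus strand) and Cd209c on chromosome 8 at 3940222 to 3954746 (minus strand). Exons of BC055324, Prrg2 and Tmem150a overlap those of Scyl3, Nosip and Rnf181 on the other strand, and the labels do not say whether the libraries kept strand.

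**Figure D2:**
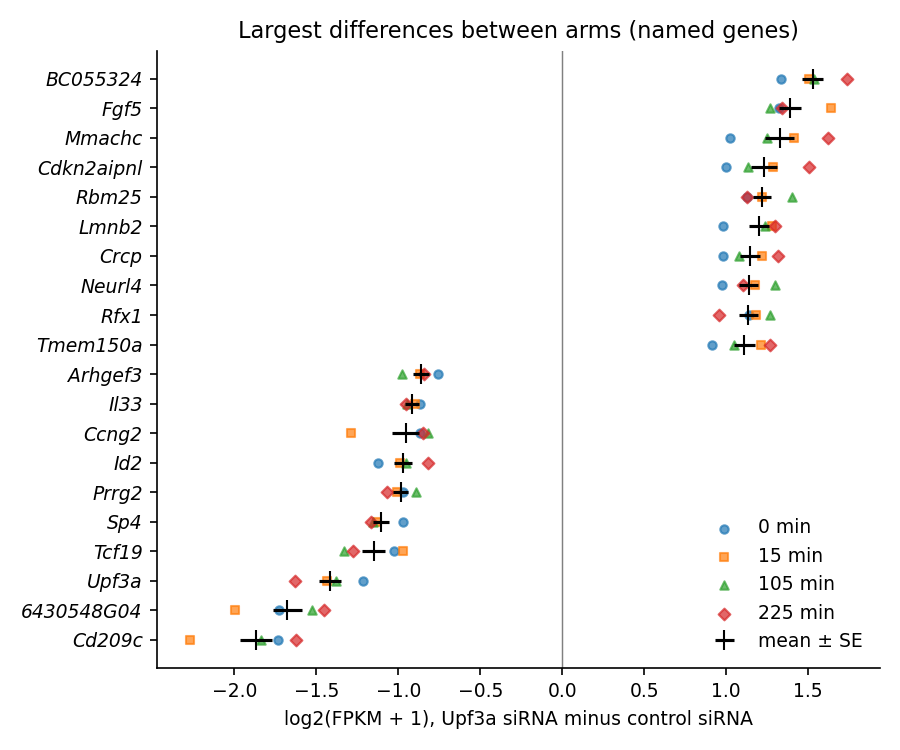
Difference in log2(FPKM + 1) between Upf3a siRNA and control siRNA for the 10 largest called increases and the 10 largest called decreases among genes with a mean FPKM of 5 or more, one sign at all times and a symbol inside the naming rule; symbols are the 4 time points and the black mark is the fitted difference ± SE. Differences run from -1.87 for Cd209c to 1.53 for BC055324.

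Of 23 cholesterol synthesis genes, 18 were lower and 1 higher, and 4 did not pass (the counts adjusted over the list alone were also 18 and 1). The list's median log2 difference was -0.27 (camera adjusted p = 1.1e-05; adjusted p = 0.44 with an estimated correlation). Hsd17b7 had a log2 difference of -0.79 (8.75 ± 0.51 to 4.64 ± 0.58 FPKM), Insig1, a sterol sensor of the pathway, of -0.48, Sc4mol of -0.47 and Idi1 of -0.46. Of 28 pluripotency genes, 14 were higher and 3 lower (14 and 3 adjusted over the list alone; camera adjusted p = 0.017; adjusted p = 0.44 with an estimated correlation). Tdgf1, the co-receptor of Nodal, averaged 103 ± 5.89 against 47.3 ± 2.41 FPKM, Dnmt3b 223 ± 51.4 against 140 ± 25.2 FPKM and Nanog 70.9 ± 10.4 against 45.3 ± 7.73 FPKM. Of 17 mesoderm and endoderm genes, 9 were higher and none lower (9 and 0 adjusted over the list alone; camera adjusted p = 0.028; adjusted p = 0.44 with an estimated correlation), among them T, or brachyury (109.5 ± 6.34 against 59.7 ± 4.64 FPKM), Lefty2 (0.73) and Eomes (0.72). This list did not pass camera when scaled to ribosomal protein genes (adjusted p = 0.062) or without length and GC trends (0.057).

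Of 26 splicing factors whose own mRNAs carry poison exons, 15 were higher and 1 lower (15 and 1 adjusted over the list alone; camera adjusted p = 0.0088; adjusted p = 0.63 with an estimated correlation). Srsf2 averaged 451 ± 74.1 against 319 ± 37.9 FPKM, and Hnrpdl, Rbm39 and Luc7l had log2 differences of 0.50, 0.45 and 0.40. Of 21 glycolysis genes, 10 were lower and 1 higher (10 and 1 adjusted over the list alone; camera adjusted p = 0.017; adjusted p = 0.62 with an estimated correlation), with Pfkp at -0.41 and Pgk1 at -0.27. Cytosolic ribosomal protein mRNAs had a median of -0.093, with 7 of 78 lower over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0013, or adjusted p = 0.81 with an estimated correlation). The list did not pass camera after quantile normalization (-0.037, adjusted p = 0.55), and its median log2 ratio was -0.15, -0.075, -0.15 and 0.039 at 0, 15, 105 and 225 min. Rpl13a was at -0.22 and Rpl11 at -0.15. Rpl11 did not pass after quantile normalization (-0.038, adjusted p = 0.41), when scaled to ribosomal protein genes (-0.072, 0.26), without 0 min (-0.13, 0.084) or without 105 min (-0.14, 0.087), over a range of adjusted p from 0.0087 to 0.41.

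The remaining lists did not pass camera, and the value in brackets after each is its camera adjusted p. Of them, the RNA decay machinery and the stress and unfolded protein response passed fry (adjusted p = 0.025 and 0.020). Adjusted over the list alone, the remaining lists' counts of higher and lower genes differed for oxidative phosphorylation (4 and 0), short-lived mRNAs (11 and 9), p53 targets (5 and 10) and the interferon list (0 and 0). Of 51 genes of the RNA decay machinery, 19 were higher and 4 lower, with the exonuclease Xrn1 at 5.27 ± 1.24 against 1.49 ± 0.49 FPKM, Pan2 at -0.36 and Zfp36 at -0.40 (list adjusted p = 0.087). Of 12 NMD factors, 2 were higher and 4 lower, with Upf2 at -0.31, Upf3b at -0.30 (-0.23 and not passing when scaled to ribosomal protein genes) and Smg1 at 0.25 (0.64; median 0.014, mean -0.023). Of 25 stress and unfolded protein response genes, 2 were higher and 10 lower, with Sesn2 at 0.46, Xbp1 at -0.40 and Mthfd2 at -0.38 (0.055). Of 46 cell cycle genes, 14 were higher and 7 lower, with Ccnd1 at 0.77, Plk1 at 0.51 and E2f1 at -0.61 (0.30). The neural list had 2 higher and 6 lower of 17, with Elavl3 at -0.79 and Dll3 at 0.62 (0.38), and the p53 target list 4 higher and 10 lower of 23, with Ei24 at 0.64 (0.30). The exon junction complex had 2 higher of 12, Casc3 at 0.42 and Acin1 at 0.25 (0.59). The short-lived mRNA list had 9 higher and 9 lower of 34, with Mycn at 0.69 (0.94; median 0.026, mean -0.0015), and oxidative phosphorylation 7 higher and 1 lower of 67, with Ndufa5 at 0.55 (0.80). Fibroblast and smooth muscle markers had 2 higher and 3 lower of 15, with Thbs1 at -0.57 and Col1a2 at -0.54 (0.67; median 0.012, mean -0.044), the interferon list 2 and 2 of 12 (0.59), and replication-dependent histones 2 lower of 10 (0.23).

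The NMD target lists addressed the design's own question. Of 23 known NMD targets, 5 were higher and 9 lower in the knockdown arm (5 and 9 adjusted over the list alone): Eif4a2 averaged 74.1 ± 8.27 against 42.9 ± 5.48 FPKM and Atf4 105 ± 29.4 against 87.0 ± 27.6 FPKM, while Ern1 was at -0.27. The list's median was -0.10, at percentile 1.68 of 10000 random lists matched on expression (permutation p = 0.034; camera adjusted p = 0.48), its mean was -0.030, and fry, which tests the list alone, gave it the direction up (adjusted p = 0.59). The median was -0.024 when scaled to ribosomal protein genes (permutation p = 0.041) and turned to 0.031 among genes with a mean FPKM of 5 or more, and the permutation p rose to 0.060 to 0.29 when any single time point was left out. Of 17 snoRNA host genes, a class in which some spliced transcripts are NMD substrates, 9 were lower and 1 higher (9 and 1 adjusted over the list alone), with Snhg7 at -0.82. Their median was -0.20, at percentile 0.01 (permutation p = 4.0e-04, camera adjusted p = 0.087, camera adjusted p = 0.69 with an estimated correlation). The estimated correlation between members was 0.19, which the permutation p takes no account of. The median was -0.12 with a pseudocount of 5 and -0.13 when scaled to ribosomal protein genes, and at 0 min the list's median log2 ratio was -0.016.

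The second comparison asked whether mRNAs were lost faster or slower after Upf3a knockdown, as the change of the log2 ratio per hour. No protein-coding or long noncoding gene passed the test. At camera's preset correlation, ribosomal protein mRNAs passed as a list with a median of 0.039 log2 units per hour in the knockdown arm over the control arm, oxidative phosphorylation mRNAs with 0.037 (-0.0018 when scaled to ribosomal protein genes) and snoRNA host genes with -0.062. With that scaling the median of all genes was -0.030, and the oxidative phosphorylation list still passed camera (adjusted p = 5.7e-06). None of these lists passed with an estimated correlation (adjusted p = 0.84 with an estimated correlation for each), and no member passed over all genes. The estimated correlations were 0.47, 0.55 and 0.0069 in the same order, against the preset 0.01. For the snoRNA host genes, correlation between members therefore does not account for the higher p. With an estimated correlation camera uses the 2 residual degrees of freedom of this fit, so not passing there is weak evidence against a list. By fry, none of these lists passed either (adjusted p = 0.71, 0.71 and 0.68). Without 225 min the medians were -0.018, -0.0075 and -0.047, and after quantile normalization 0.0076, 0.0073 and -0.050. Known NMD targets stood within the range of random lists.

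Of 11452 genes, limma called 1, the small RNA gene Mir3096 (chosen after its values were seen), and 762 had an unadjusted p below 0.05. limma with trend and robust called 6, without Mir3096. The gene was listed at 0 FPKM in 5 of the 8 conditions. With simulated differences of 0.3 log2 units per hour, 90% of changed genes were recovered, and 0% at 0.1, so small differences of single genes were not detectable here. The calls numbered 22 without 0 min, 2 without 15 min, 7 without 105 min and 10 without 225 min.

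Ranked by moderated t, Cdkn2d, an inhibitor of cyclin-dependent kinases, had a slope of -0.41 log2 units per hour in the knockdown arm and -0.13 in the control arm (difference -0.28 ± 0.03 SE, adjusted p = 0.14). Differences were -0.18 for Rprm, -0.17 for the transcription factor Foxd3, -0.17 for Ddx28, -0.17 for Dpp3, -0.16 for Myc and -0.16 for Pelo, a ribosome rescue factor. In the other direction they were 0.23 for Ass1, 0.16 for Cyr61, 0.14 for Ndufab1, 0.14 for Uqcrc2 and 0.12 for Pdk3. Upf3a stood at -0.084 and Upf3b at -0.016, and none of these genes passed (adjusted p 0.14 to 0.94). Cdkn2d passed with trend and robust (adjusted p = 0.0056) and without 0 min (0.048), over a range of adjusted p from 0.0056 to 1.0 across its alternatives.

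The gain of the 78 ribosomal protein mRNAs passed camera (median 0.039, camera adjusted p = 1.5e-07; adjusted p = 0.84 with an estimated correlation), with Rpl30 at 0.12. So did that of the 67 oxidative phosphorylation mRNAs (median 0.037, camera adjusted p = 1.1e-06, adjusted p = 0.84 with an estimated correlation), with Ndufs7 at 0.13. When scaled to ribosomal protein genes the list's median was -0.0018, where that of all genes was -0.030, and the camera call was kept. The 46 cell cycle mRNAs gained 0.021, or -0.018 when scaled to ribosomal protein genes (camera adjusted p = 0.0062; adjusted p = 0.84 with an estimated correlation), with Pcna at 0.076. No member of these lists passed over all genes or adjusted over the list alone. Without the 225 min time point the cell cycle median was 0.0035 (camera adjusted p = 0.68), and none of the 4 list calls was made. After quantile normalization it was 0.0040, and the calls of these 3 lists were not made (adjusted p = 0.42).

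The 17 snoRNA host genes lost a median of 0.062 log2 units per hour more in the knockdown arm (median difference -0.062, camera adjusted p = 1.2e-04; adjusted p = 0.84 with an estimated correlation). Their median log2 ratio was -0.016 at 0 min, -0.060 at 15 min, -0.22 at 105 min and -0.34 at 225 min. No member passed over all genes and 4 were lower adjusted over the list alone; Snhg12 stood at -0.17, Snhg5 at -0.10 and Snhg3 at -0.099. The list's median lay below that of all 10000 random lists (permutation p = 2.0e-04, the smallest they can give). With time linear in each arm camera's adjusted p was 0.12, and without 225 min it was 0.39. The median was -0.038 with a pseudocount of 5 and -0.037 without length and GC trends, and the call was kept. Known NMD targets had a median of -0.0061, at percentile 17.4 (permutation p = 0.35) and a mean of 0.0037, and without 225 min the median was 0.033, with Arc at -0.11 and Gadd45a at 0.096. The NMD factor list had a median of -0.021 (camera adjusted p = 0.16), with Pnrc2 at -0.12, and the short-lived mRNA list -0.029 (0.062). The other lists had camera adjusted p of 0.21 to 0.91 and no member called, and the median and mean of the fibroblast and smooth muscle list differed in sign (0.0091 and -6.0e-04).

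**Figure D3:**
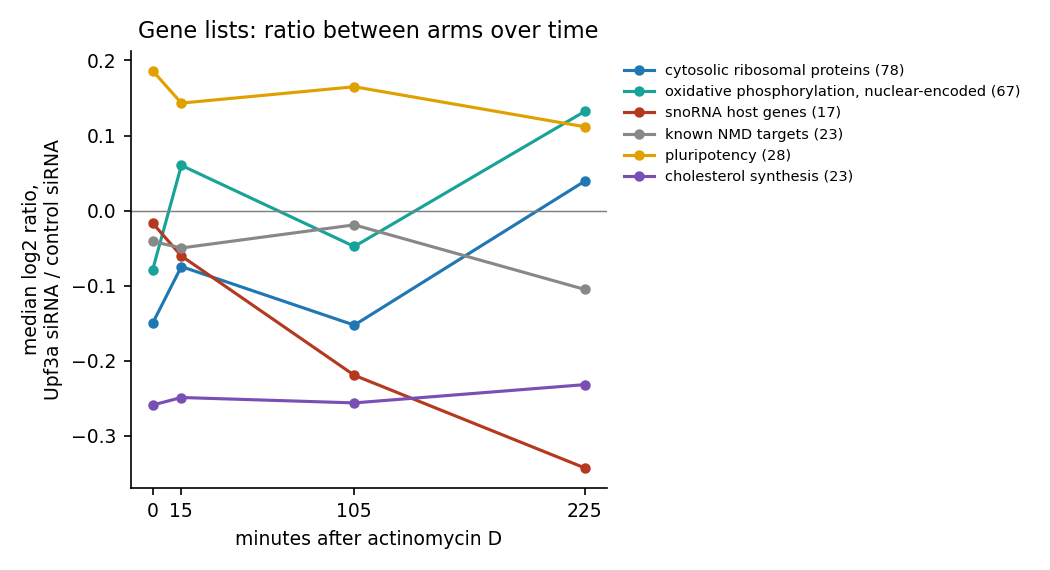
Median log2 ratio of Upf3a siRNA to control siRNA for 6 gene lists against minutes after actinomycin D; the number of genes tested is in brackets, and each point is a median over genes at 1 time point. The snoRNA host genes go from -0.016 to -0.34, and the ribosomal protein list lies at 0.039 at 225 min.

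The third description covers the loss of mRNAs in both arms after the block. Nodal, a signalling ligand of the early embryo, fell fastest among the named genes, at -1.16 ± 0.09 (SE) log2 units per hour, a relative half-life of 0.86 h (chromosome 10, 61417972 to 61425338, plus strand). The transcription factor Irf1 (1.07 h), Cyr61 (1.11 h), the kinase Sgk1 (1.12 h) and Pnrc1 (1.14 h) followed, then Fbxo5 (1.16 h), the amino acid transporter Slc38a2 (1.16 h), the mitotic inhibitor Wee1 (1.17 h) and the phosphatases Dusp1 (1.19 h) and Dusp6 (1.21 h). Half-lives and their order depend on the settings: from leaving out 225 min to a pseudocount of 5, the slope ran from -1.64 to -0.88 for Nodal, -1.60 to -0.69 for Irf1, -1.60 to -0.62 for Cyr61, -1.45 to -0.53 for Dusp1 and -1.48 to -0.60 for Dusp6. Relative to the rest, 77 of 78 ribosomal protein, 66 of 67 oxidative phosphorylation and 18 of 21 glycolysis mRNAs rose. The medians of the latter lists were -0.040 and -0.11 when scaled to ribosomal protein genes, where that of all genes was -0.23. Both lists stayed above that bulk with that scaling (camera adjusted p = 2.5e-44 and 0.0011). As lists they passed camera at its preset correlation and fry (fry adjusted p = 4.1e-05, 4.1e-05 and 2.5e-06). They did not pass camera with an estimated correlation (adjusted p = 0.51, 0.51 and 0.39). After quantile normalization the medians of the 3 lists were 0.019 (camera adjusted p = 0.50), 0.073 (6.1e-04) and -0.0055 (0.69). That normalization partly removes a shared rise of the most abundant mRNAs by construction. Slopes are relative to the bulk of the transcriptome, since FPKM has no outside standard, so a rise here is a rise relative to that bulk.

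limma called 9314 of 11452 genes, 4891 rising and 4423 falling. Slopes of the arms correlated across genes at Pearson r = 0.91 and Spearman rho = 0.97, where genes are not independent replicates, and 281 genes had a relative half-life under 2 h in both arms. At 225 min, 1642 genes in the control arm and 1876 in the knockdown arm had lost 1 log2 unit or more from 0 min, against 18 and 17 at 15 min. Scaled to ribosomal protein genes instead, the median slope of all genes shifted by -0.25 log2 units per hour and 0.44% of the called genes rose, against 52.5% as deposited.

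All 34 short-lived mRNAs tested fell (34 adjusted over the list alone; median -0.55 log2 units per hour, camera adjusted p = 1.6e-07; adjusted p = 0.74 with an estimated correlation), with Mycn at a half-life of 1.30 h, Id2 at 1.43 h and Mcl1 at 1.97 h. Of 78 ribosomal protein mRNAs, 77 rose (78 adjusted over the list alone; median 0.30, camera adjusted p = 8.9e-18; adjusted p = 0.51 with an estimated correlation), among them Rpl36 (0.42), Rps21 (0.38), Rplp2 (0.38) and Rps19 (0.33). Over the alternatives these went as low as 0.071 for Rpl36 and 0.034 for Rps19, and Rplp2 did not pass after quantile normalization (0.046, adjusted p = 0.11). Of 67 oxidative phosphorylation mRNAs, 66 rose (66 adjusted over the list alone, median 0.25, camera adjusted p = 1.0e-14, or adjusted p = 0.51 with an estimated correlation), among them Cox8a (0.43), Atp5d (0.39) and Ndufa1 (0.33). Over the alternatives these went as low as 0.13 for Cox8a, 0.094 for Atp5d and 0.039 for Ndufa1. Of 21 glycolysis mRNAs, 18 rose and 1 fell (18 and 1 adjusted over the list alone; median 0.18, camera adjusted p = 4.2e-04; adjusted p = 0.39 with an estimated correlation), with Pkm2 at 0.25 and Pfkl at 0.23, or -0.044 and -0.065 when scaled to ribosomal protein genes. The median of the short-lived list was -0.91 without 225 min, -0.33 with a pseudocount of 5 and -0.79 when scaled to ribosomal protein genes, where the list did not pass camera (adjusted p = 0.67).

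Scand1 rose most among the named genes (0.58 ± 0.09 log2 units per hour), with the histone genes Hist1h4d (0.46), Hist1h3c (0.40) and Hist3h2ba (0.38), which did not pass when scaled to ribosomal protein genes (0.20, 0.14 and 0.11). Without 225 min Hist1h4d (0.59, adjusted p = 0.072) and Hist1h3c (0.37, 0.13) did not pass either. Of 28 pluripotency genes 8 rose and 16 fell (9 and 16 adjusted over the list alone; median -0.064, camera adjusted p = 0.32). Pou5f1 rose by 0.27 log2 units per hour, but did not pass when scaled to ribosomal protein genes (-0.026, adjusted p = 0.13) or after quantile normalization (adjusted p = 0.96). Of 25 stress and unfolded protein response mRNAs 14 rose and 8 fell (14 and 8 adjusted over the list alone; median 0.047, camera adjusted p = 0.69), and Xbp1 fell with a half-life of 1.47 h and Trib3 with 2.36 h. The licensing factor Cdt1 (1.63 h), Eomes (2.06 h) and the NMD factor Pnrc2 (1.58 h) also fell, where 19 of 46 cell cycle genes rose and 15 fell (19 and 14 adjusted over the list alone) and 7 of 12 NMD factors rose and 4 fell (7 and 4 adjusted over the list alone). Of 10 histone genes 8 rose (camera adjusted p = 0.070), and of 15 fibroblast and smooth muscle markers 12 rose and 3 fell (0.070). The lists of NMD factors, RNA decay machinery, stress response, interferon response, cell cycle, neural differentiation and splicing factors had a positive median and a negative mean, and none passed (0.69 to 0.95). Upf3b rose by 0.17 log2 units per hour, -0.11 when scaled to ribosomal protein genes, and did not pass without 225 min (0.11, adjusted p = 0.077).

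**Figure D4:**
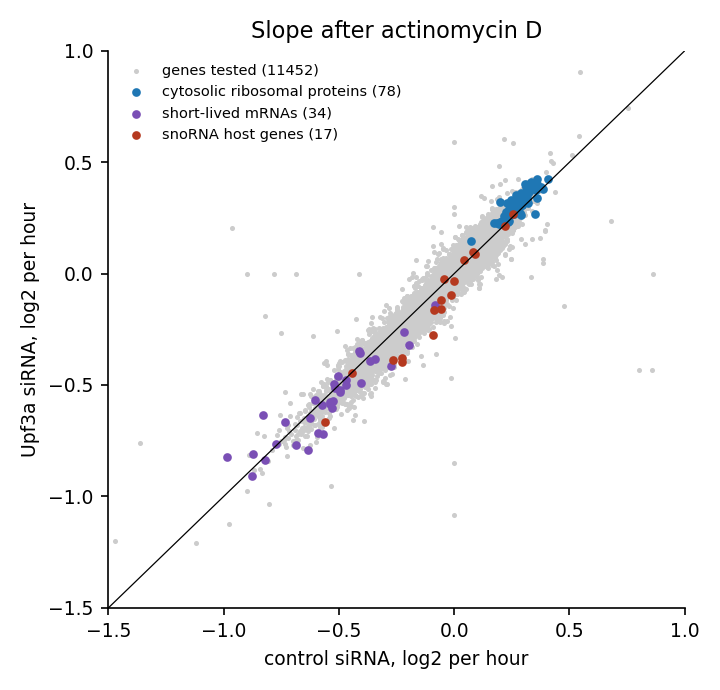
Slope of log2(FPKM + 1) per hour after actinomycin D in the Upf3a siRNA arm against the control siRNA arm, 1 point per gene tested, with 3 gene lists in colour and the line of equal slopes in black; 11 genes lie outside the axes. Short-lived mRNAs lie at the lower left (median -0.55 over both arms) and ribosomal protein mRNAs at the upper right (median 0.30).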

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

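The tests of the 225 min libraries, of NMD targets in general against the snoRNA hosts, and the removal of length and GC trends were chosen after the results were seen. Apart from the difference in level, each result came from a test of whether the difference between the arms changed with time.

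Ribosomal protein mRNAs gained a median of 0.039 and oxidative phosphorylation mRNAs 0.037 log2 units per hour in the knockdown arm over the control arm (adjusted p = 0.84 with an estimated correlation for both). The 105 min libraries alone do not account for it, since without them the medians were 0.044 and 0.037. Without the 225 min libraries they were -0.018 and -0.0075, so the gain rests on that time point. Both lists lay inside the range of random lists matched on the decay rate in both arms, at percentiles 90.4 and 90.5, so a common decay course that had run further in the knockdown libraries at 225 min may account for the gain; without length and GC trends the medians were 0.017 and 0.015, with the camera adjusted p at 0.088 for both. A change in stability through UPF3A stays open and was not tested apart from this.

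The snoRNA host genes lost more per hour in the knockdown arm, with a median of -0.062, or -0.037 without length and GC trends and -0.038 with a pseudocount of 5 (adjusted p = 0.84 with an estimated correlation). Random lists matched on the decay rate did not reproduce it: the median lay at percentile 0 of them. The match was on 1 slope over all times, and Gas5 and Snhg12 fell and then partly rose in the control arm. Uneven progress along a course of that shape is therefore not excluded. Leaving out 1 member moved the median no closer to 0 than -0.046, though a median moves little when 1 member is dropped. Without 225 min the median was -0.047, but the camera adjusted p was then 0.39, so the list call was not made without that time point. Known NMD targets outside this list lay at percentile 17.4, inside the range of random lists, so faster decay of NMD targets in general cannot be told apart from none with 23 genes. A candidate explanation is faster loss of spliced host transcripts when UPF3A is low, which was not tested here, while reads of the snoRNAs inside these genes, transfection differences and off-target effects of the siRNA stay open.

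The difference in level between the arms covered 5543 genes. Length or GC bias does not account for it as a whole: 91.0% of the called genes with a GENCODE match kept the call and its sign once those trends were removed. Of the 8 ways to swap the arm labels within time points, 1 gave as many calls, the real one, and the highest of the others gave 0; 8 ways are too few for a share under 0.05. A difference between transfections or cultures that was shared by the time points of an arm, an off-target effect of the siRNA and a lower level of UPF3A, which was not measured as protein, may each give such a pattern, and the design cannot separate them.

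The cell cycle list gained a median of 0.021 log2 units per hour in the knockdown arm (adjusted p = 0.84 with an estimated correlation), which was 0.0035 without 225 min and -0.018 when scaled to ribosomal protein genes. The single gene called for the decay rate difference was Mir3096, at 5.50 log2 units per hour (limma adjusted p = 1.4e-04), and it was listed at 849 and 812 FPKM in the control arm at 0 and 15 min, at 1191 FPKM in the knockdown arm at 225 min and at 0 in the other 5 conditions. Of the 8 ways to swap labels, 3 gave as many calls for the decay rate difference, with 1 call for the real labels and 1 as the highest of the others, too few ways for a share under 0.05.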

How the results depend on the processing

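The authors' limits, the removal of length and GC trends and leaving out small RNA genes were tests chosen after the results were seen. No paired analysis was possible because the table holds 1 value per condition and so no cultures to pair (the arms were compared within time points), and the replicate block and the fits without 1 replicate were not run, nor were the authors' q-value thresholds. The count for the expression difference stayed between 3951 and 6543 over the alternatives fitted with limma, and was 43 by the authors' limits. That for the decay rate in both arms stayed between 6795 and 10744, but scaled to ribosomal protein genes 47 rose and 10695 fell. The Upf3a difference kept its sign and call, at -1.58 with a pseudocount of 0.1 and -1.48 to -1.35 without 1 time point. Over all its alternatives it ran from -1.58 to -0.98. The count for the decay rate difference was 0 without a filter, with time linear in each arm and without small RNA genes, 6 with trend and robust (0 of them shared) and 2 to 22 in leave-one-out. Known NMD targets' median expression difference was -0.038 with a pseudocount of 5, -0.068 without a filter, 0.031 at a mean FPKM of 5 or more, -0.089 after quantile normalization, -0.024 when scaled to ribosomal protein genes, -0.030 as a mean and -0.090 to -0.051 in leave-one-out. Their decay rate difference turned to 0.0078 with a pseudocount of 5, 0.012 at a mean FPKM of 5 or more, 0.0035 without length and GC trends and 0.0037 as a mean, and ran from -0.0083 to 0.033 in leave-one-out. Lists called for the expression difference numbered 0 with an estimated correlation and 7 with fry, 5 of them shared with camera at its preset correlation. For the decay rate difference they were 1 after quantile normalization, 2 without length and GC trends, 0 with an estimated correlation or fry, and 0 to 5 in leave-one-out. For the decay rate in both arms they were 7 without a filter, 8 at an adjusted p below 0.1, 0 with an estimated correlation, 13 with fry and 4 to 8 in leave-one-out. Decay rate differences that turned were 0.0023 for Upf3b after quantile normalization, and, scaled to ribosomal protein genes, -0.018 for the cell cycle and -0.0018 for the oxidative phosphorylation list. With that scaling the median of all genes was -0.030. The oxidative phosphorylation list kept its camera call (adjusted p = 5.7e-06), while the cell cycle list did not (0.14). In leave-one-out Upf3b ran from -0.061 to 0.033, the ribosomal protein list from -0.018 to 0.052 and the oxidative phosphorylation list from -0.0075 to 0.058, each with its turned sign without 225 min, and Upf3b also without 0 min (0.027). Slopes in both arms turned after quantile normalization to -0.0055 for the glycolysis list, -0.029 for Pkm2 and -0.019 for Snhg1. Scaled to ribosomal protein genes they turned to -0.11 for the glycolysis list, -0.040 for the oxidative phosphorylation list, -0.044 for Pkm2, -0.065 for Pfkl, -0.026 for Pou5f1, -0.077 for Snhg1 and -0.11 for Upf3b. Genes that decay less than ribosomal protein genes were the only ones left rising, by construction. The median of all genes was then -0.23, and the glycolysis and oxidative phosphorylation lists kept their camera calls (adjusted p = 0.0011 and 2.5e-44). Fewer genes were tested at a mean FPKM of 5 or more, and for the other changes the cause was not tested. Depth is unknown, so its limit on low genes cannot be given.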

Other observations

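The tests on the 3' UTR with the decay rate held fixed and without 225 min were chosen after the result was seen. Of 23 known NMD targets 13 fell and 6 rose over both arms, and the list did not pass camera (adjusted p = 0.32; adjusted p = 0.88 with an estimated correlation). The median slope was -0.16 log2 units per hour, and it lay at percentile 0.42 of random lists matched on expression (permutation p = 0.0086, which takes no account of correlation between genes), with Atf4 at a relative half-life of 3.62 h. Of 23 p53 targets 15 fell and 4 rose (median -0.077, camera adjusted p = 0.070), and of 17 mesoderm and endoderm mRNAs 11 fell and 2 rose (median -0.25, camera adjusted p = 0.063). The snoRNA hosts took different courses: Snhg5 fell with a half-life of 1.63 h, Snhg1 rose by 0.22 log2 units per hour (-0.077 when scaled to ribosomal protein genes), and Gas5, with a half-life of 3.06 h over the whole course (not passing without 0 min or without 15 min, adjusted p = 0.12 and 0.076), went from 18.4 FPKM at 0 min to 6.82 at 105 min and 9.37 at 225 min in the control arm, and from 21.7 to 5.69 and 7.28 in the knockdown arm. Snhg12 likewise stood at 32.5, 11.9 and 18.4 FPKM in the control arm and at 36.0, 11.2 and 12.0 in the knockdown arm.

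One hypothesis was that genes with an annotated NMD transcript change when UPF3A is low. The 3278 such genes had a median decay rate difference of 0.0048 log2 units per hour, at percentile 90.9 of 2000 random lists matched on expression, and a median expression difference of 0.015, at percentile 90.65. Both lay inside the range of random lists and close to their medians of 0.0038 and 0.0087, so gene-level values gave no sign of a shift; single isoforms were not analysed here.

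Another hypothesis was that 3' UTR length goes with stability. Across 10956 genes, Spearman's rho of 3' UTR length and the decay rate in both arms was -0.36: the 2740 genes with the shortest UTRs (up to 485 nt) had a median slope of 0.11 and the 2740 with the longest (2266 nt or more) of -0.078 log2 units per hour. With the decay rate difference rho was -0.18, which fell to -0.034 with the decay rate in both arms held fixed and was 0.067 without the 225 min time point. The relation with the difference may therefore follow from the common decay course at 225 min rather than from UPF3A. Neither relation was tested with transcript length or GC content held fixed, and 3' UTR length is part of transcript length. Genes are not independent replicates, and no p is given.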
